A study of Mus musculus with 6 samples.

How the data were processed

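RNA was taken from mid-ventricular heart tissue of 3 WT and 3 TET2KO mice after 28 days of Angiotensin II at 1 mg/kg/day, and poly(A)-selected libraries were sequenced as read pairs of 150 nt on an Illumina NovaSeq, per the labels' protocols. All 6 libraries carry the same batch label. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2, and the builds GRCm38 and mm10. The annotation release and the strand setting of the counting are not given in the sources used here.

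The authors deposited raw read counts per Ensembl gene, whole numbers without normalization, for 49315 genes in the 6 libraries. They also deposited TPM values, scaled to the same total in each library. Their comparison table holds log2 fold changes of TET2KO over WT, p-values and adjusted p-values, per the file headers. Its library columns are a normalised signal: the authors divided the counts by 1 size factor per library, as the constant ratio to the raw counts shows. A second table of the authors holds the log2 fold changes and p-values of the genes they list as significant. Libraries were matched to samples by the library names in the descriptions, and no column of per-sample values was left unmatched (0).

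The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, robust fit) on the deposited counts, with TMM normalization, filterByExpr on the groups, group as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors are on the log2 scale and were worked back from the test, as the absolute log2 fold change over the square root of F. CPM values use the TMM factors. Gene symbols are those of the authors' deposited count table, where 174 of the 49315 gene IDs have none. Positions, transcript lengths and GC content come from GENCODE M21 (GRCm38), to which 49056 of these IDs matched. Length and GC are those of the longest transcript, protein-coding where the gene has one. A total of 40 gene lists was fixed before the data were examined, of which 39 had at least 5 tested members; the list of sex-linked transcripts had 4 and was not tested, with 0 higher and 1 lower (1 higher and 2 lower adjusted over the list alone). Lists were tested with camera at the preset inter-gene correlation of 0.01, and with an estimated correlation and fry (limma 3.58.1) as alternatives.

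Named genes were also fixed by rule before the data were examined. They are Tet1, Tet2 and Tet3; Nppa, Nppb, Myh7, Acta1, Col1a1, Col3a1, Postn, Pecam1 and Cdh5; the 8 largest rises and 8 largest falls among genes past the test with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out predicted genes, unnamed genes, clone names and symbols marked as pseudogenes; and the members with the smallest p past the test, up to 4 from each list past camera and up to 2 from each other list. From a list past camera with no such member, the rule would have taken the 2 with the smallest p. Where fewer than 3 genes passed in a direction, the rule would have taken the 5 with the smallest p under the same filters. A sign change under an alternative was counted as a reversal where the value passed the test in either fit.

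The trend on transcript length and GC was fitted for each library with a smooth surface (mgcv 1.9.3, basis size 6 per axis) to the deviation of each gene's log2 CPM, with a prior count of 2, from its mean over the libraries, and entered the edgeR fit as offsets. A second version used the length of all exons of a gene merged. The trend takes out any real difference that follows length or GC along with a technical one.

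The fits were tested on simulated counts drawn from the real means and library sizes. Without a trend, the fit recovered 30% of 100 genes changed by a log2 fold of 1 and 93% of 100 changed by 2, with 6 unchanged genes called among 14166 tested. With a length and GC trend added, the fit called 6406 unchanged genes among 14146. With the trend removed it called 12 and recovered 82% and 99%. The trend added was the surface fitted to these data on the same lengths, so removal was not tested where lengths are wrong. These counts were drawn with the dispersions of the trend-removed fit, and those without a trend with the dispersions of the main fit. The recovered shares are therefore not comparable between the 2 simulations. In counts drawn without a trend and independently for each gene, a list of immediate early genes shifted by a log2 fold of 1 was the only list called (1). That simulation cannot show how camera behaves where genes vary together or follow length.

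Library totals were 24280314, 26569073 and 22124844 reads for WT replicates 1, 2 and 3, and 30418909, 26810691 and 27514747 for TET2KO replicates 1, 2 and 3. TMM factors were 0.859, 0.922 and 0.808 for WT and 1.22, 1.12 and 1.15 for TET2KO. The gene with the most counts in each library, mt-Co1, took 6.44 to 8.24% of them. Counts of replicates differed beyond sampling noise for every pair (chi-square per degree of freedom 13.2 to 298 within groups), so no library was counted as a copy of another. Counts of genes at a few reads per library carry counting error that the test includes.

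Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical genes, such as the globin genes, Myh6 and Myh7, and mitochondrial genes with nuclear copies, may be split; their values are uncertain to that extent. The alternatives were DESeq2 size factors, total library size, no count filter, a filter of 1 CPM in 3 samples, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom with and without sample quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, leaving out each library, leaving out mitochondrial transcripts, and stricter thresholds. Removal of the length and GC trend, in both versions and with single libraries left out, and the gene lists at total library size were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.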

Results

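Messenger RNA was measured in mid-ventricular heart tissue of mice that had received Angiotensin II, the vasoconstrictor peptide of the renin-angiotensin system, at 1 mg/kg/day for 28 days from osmotic minipumps. There were 2 groups of 3 libraries each. One is labelled wild type (WT), and the other a knockout, specific to endothelial cells, of Tet2, a dioxygenase that oxidises 5-methylcytosine in DNA (TET2KO). The design text calls the samples of a group biological replicates. The deposited counts summed to between 22124844 and 30418909 reads per library, and 14370 of 49315 genes were tested. Levels are CPM, read counts scaled to a common library size (mean ± SD, n = 3 per group). Log2 fold changes are TET2KO over WT ± SE, with p-values from edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. A second estimate, with a trend on transcript length and GC content removed, was chosen after the data had been seen and is given as the trend-removed value.

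Tet2 itself was compared first, as a check of the labels. Tet2 (ENSMUSG00000040943, GRCm38 chromosome 3, 133463679 to 133545139, minus strand, protein coding) stood at 3.90 ± 0.707 CPM in the libraries labelled WT and 11.0 ± 3.35 CPM in those labelled TET2KO. It was 2.82-fold higher in the libraries labelled TET2KO, against the labels (log2 fold change 1.49 ± 0.29, adjusted p = 0.0065). The libraries labelled WT held 4.27, 4.33 and 3.08 CPM and those labelled TET2KO 14.6, 8.01 and 10.4 CPM, so the groups did not overlap. The trend-removed value of 0.27 ± 0.17 did not pass the test (adjusted p = 0.21, range over 19 alternatives 2.1e-06 to 0.21). Which exons were deleted is not given in the sources used here, and the deletion concerns endothelial cells within whole tissue, so gene-level counts may not show it. Every direction below is that of the labels, which Tet2 went against.

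Genes of DNA methylation and demethylation were compared next. Of 12 tested members of this list, Tet2 included, 7 were higher, 0 lower and 5 not past the test (7 higher and 0 lower adjusted over the list alone). Dnmt3a, a de novo DNA methyltransferase, rose from 3.61 ± 0.395 to 19.7 ± 10.3 CPM (log2 fold change 2.44 ± 0.40, adjusted p = 0.0065, trend-removed 0.51 ± 0.16). Tet1 and Tet3, the other dioxygenases of the family, rose by 1.57 ± 0.42 and 2.18 ± 0.62 on the log2 scale (adjusted p = 0.013 and 0.017). Their trend-removed values of 0.30 ± 0.28 and -0.013 ± 0.27 did not pass. Without WT replicate 2 or without WT replicate 3 neither gene passed, where the log2 fold change of Tet1 was 1.45 and 1.52 and the log2 fold change of Tet3 was 2.19 and 1.94. The list did not pass camera, a test of a list against the other genes (adjusted p = 0.096), and had 1 higher and 0 lower members after trend removal.

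Across all genes, 9037 of 14370 (62.9%) differed between the libraries labelled TET2KO and those labelled WT, 4806 higher and 4231 lower in TET2KO. By the rule for named genes, the largest rises included Bcl9l, a co-activator of beta-catenin (log2 fold change 4.57 ± 0.75), and Atp1b2, a subunit of the sodium pump (4.27 ± 0.63). They also included Piezo1, a mechanically gated ion channel (4.17 ± 0.75), and Plec, which encodes the cytoskeletal linker plectin (4.11 ± 0.76). Bcl9l, Atp1b2, Piezo1 and Plec stood at means of 0.403, 0.577, 0.662 and 5.11 CPM in WT and 9.55, 11.2, 12.2 and 87.5 CPM in TET2KO. All but Plec were thus near the floor in WT, where Bcl9l had 5, 10 and 10 reads. Each was lowest in replicate 2 of the TET2KO libraries. The largest falls included the beta-globin genes Hbb-bs (-3.62 ± 0.81) and Hbb-bt (-3.33 ± 0.73), Rgs18, a regulator of G-protein signalling (-3.25 ± 0.53), and Nppb, which encodes B-type natriuretic peptide (-2.23 ± 0.39). Trend-removed values were 2.04 ± 0.30, 3.99 ± 0.58, 1.59 ± 0.28 and 1.54 ± 0.22 for these rises and -2.57 ± 0.59, -2.28 ± 0.53, -2.17 ± 0.38 and -1.01 ± 0.22 for these falls, each past the test. Of the calls, 6125 had an absolute log2 fold change of at least 1. Among all 14370 tested genes the groups did not overlap in 10561 (73.5%). A random order of the libraries would give 10% for any single gene. Genes of the same libraries vary together, so the excess over 10% is not a test. Scaling by total library size moved the median of all genes from 0.046 to 0.47 and made 74.2% of the calls higher, against 53.2% with TMM factors. On log2(TPM + 1) values 79.6% were higher. Lower genes numbered 2771 without WT replicate 3 and 2479 without TET2KO replicate 3.

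Fold changes followed transcript length. In the 1435 genes with the shortest transcripts (up to 1094 nt) the median log2 fold change was -1.29, with 35 genes higher and 1050 lower. In the 1434 with the longest (from 6549 nt) it was 1.38, with 1039 higher and 54 lower. Spearman's rho of the fold change was 0.61 with transcript length and 0.26 with GC content across 14341 genes, which are not independent replicates, and a smooth trend on both took up 58.0% of the variance. The libraries labelled TET2KO differed in this. Against the WT mean, the longest group stood at 1.82, 0.61 and 1.43 and the shortest at -1.68, -0.80 and -1.36 in TET2KO replicates 1, 2 and 3. TET2KO replicate 2 stood apart from the other 2: it correlated more closely across genes with WT replicate 2 (Pearson's r = 0.968) than with TET2KO replicate 1 (0.928). After trend removal 6647 genes passed the test, 3150 higher and 3497 lower. Of these, 4942 passed in both fits, 4712 of them in the same direction and 230 in the opposite one. Without TET2KO replicate 2 the count was 11178 as counted and 8672 after trend removal. The latter was 4221 without WT replicate 1, 4259 without WT replicate 3 and 4036 without TET2KO replicate 3.

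**Figure D1:**
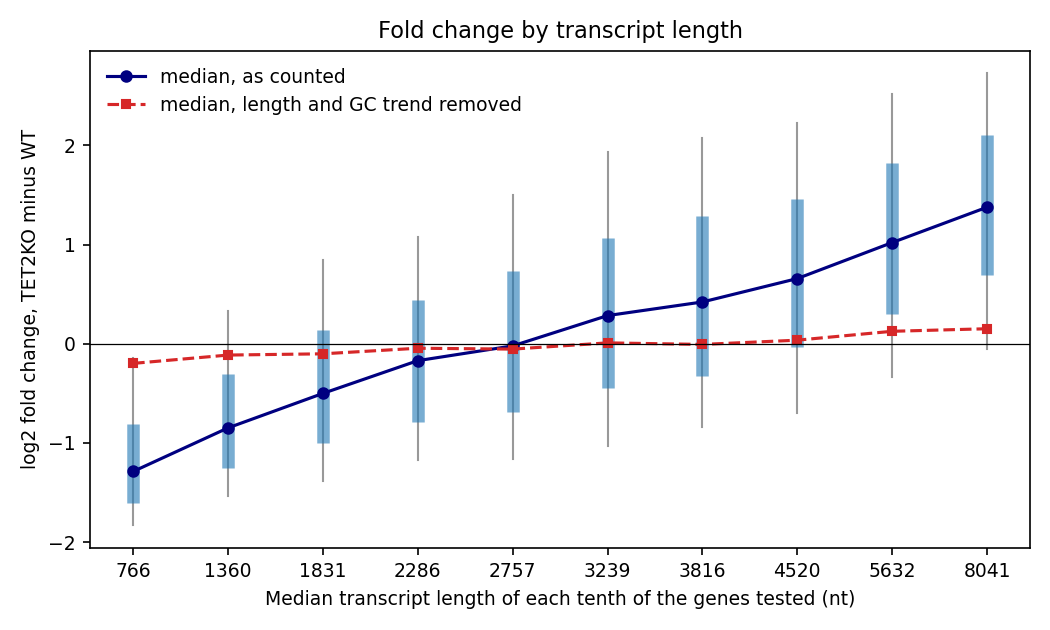
Log2 fold change (TET2KO minus WT) in 10 groups of genes ordered by transcript length in nucleotides, where dots are medians, thick bars the quartiles, thin lines the 10th to 90th percentiles of the genes, and squares the medians with the length and GC trend removed. The medians run from -1.29 in the shortest group to 1.38 in the longest, and from -0.20 to 0.15 with the trend removed.

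Of 22 pan-endothelial markers, of the cell type in which Tet2 was to be deleted, 15 were higher, 5 lower and 2 not past the test (15 higher and 5 lower adjusted over the list alone) in the libraries labelled TET2KO. Cdh5, which encodes VE-cadherin of endothelial junctions, rose from 12.6 ± 2.43 to 133 ± 84.5 CPM (log2 fold change 3.40 ± 0.53, adjusted p = 0.0065), and Pecam1 (CD31) from 54.8 ± 4.25 to 146 ± 37.7 CPM (1.41 ± 0.23, adjusted p = 0.0065). Sox18, an endothelial transcription factor, rose by 2.12 ± 0.33 and Tie1, a receptor kinase, by 2.27 ± 0.36 on the log2 scale. Trend-removed values of these 4 genes were 2.47 ± 0.36, 1.03 ± 0.15, 2.00 ± 0.28 and 0.53 ± 0.13, each past the test. The list median was 1.57 (camera adjusted p = 0.012, adjusted p = 0.86 with an estimated correlation). It was 0.50 after trend removal, where 11 higher and 2 lower members were counted and the list passed camera (adjusted p = 0.96 with an estimated correlation). Cdh5 stood at 215, 46.1 and 138 CPM in TET2KO replicates 1, 2 and 3. With limma-voom and on log2(TPM + 1) values the list did not pass camera (adjusted p = 0.051 and 0.10, range over 19 alternatives 5.3e-06 to 0.11).

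Genes of angiogenesis and Notch signalling were mostly higher in the libraries labelled TET2KO. Of 30, 22 were higher, 0 lower and 8 not past the test (22 higher and 1 lower adjusted over the list alone). Pdgfb, the growth factor that recruits pericytes, rose by 2.18 ± 0.31 on the log2 scale, the Notch ligand gene Jag2 by 2.39 ± 0.38, the peptide hormone gene Apln by 1.22 ± 0.20 and the VEGF co-receptor gene Nrp2 by 2.60 ± 0.50. Pdgfb, Apln and Nrp2 had trend-removed values of 0.82 ± 0.13, 0.81 ± 0.14 and 0.94 ± 0.22, past the test, and Jag2 one of 0.10 ± 0.18. The list median was 1.15 (camera adjusted p = 0.00074, adjusted p = 0.86 with an estimated correlation) and 0.45 after trend removal, where 14 higher and 1 lower members were counted and the list passed camera (adjusted p = 0.96 with an estimated correlation). The endothelial activation and vasomotor list had 10 higher and 2 lower of 22 (10 and 2 adjusted over the list alone, camera adjusted p = 0.11). After trend removal it had 10 higher and 0 lower members and passed camera (adjusted p = 0.96 with an estimated correlation). Its members Ece1, the endothelin-converting enzyme, and Ednra, an endothelin receptor, rose by 2.34 ± 0.40 and 1.70 ± 0.31 (trend-removed 0.74 ± 0.16 and 1.54 ± 0.28). Markers of capillary, arterial, venous and endocardial cells had 8 higher and 7 lower of 22 (8 and 7 adjusted over the list alone, camera adjusted p = 0.99), with a median of 0.28 and a mean of 0.19 against a downward camera direction. Among them were Sema3g of arterial cells (2.73 ± 0.42, trend-removed 1.05 ± 0.20) and Cytl1 (-1.32 ± 0.27), whose trend-removed value of -0.31 ± 0.14 did not pass the test. After trend removal 3 higher and 4 lower members of this last list were counted, and its median turned to -0.21.

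Basement membrane genes were mostly higher in the libraries labelled TET2KO. Of 14, 13 were higher, 0 lower and 1 not past the test (13 higher and 0 lower adjusted over the list alone). Col4a2 and Col4a1, the type IV collagen chains, rose by 3.58 ± 0.67 and 3.09 ± 0.63 on the log2 scale, and Lamb2, a laminin chain, by 2.21 ± 0.44. The list median was 2.08 (camera adjusted p = 0.00074, adjusted p = 0.86 with an estimated correlation). Trend-removed values were 0.95 ± 0.20, 0.68 ± 0.21 and, for Lamb2, -0.020 ± 0.11. After trend removal 5 higher and 3 lower members were counted, with a median of 0.38, and the list did not pass camera. The median transcript of this list is 6270.5 nt long.

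Of 39 fibrillar collagen and matrix genes, 23 were higher, 4 lower and 12 not past the test (23 higher and 4 lower adjusted over the list alone) in the libraries labelled TET2KO. Bgn, which encodes the small proteoglycan biglycan, rose from 16.0 ± 1.80 to 160 ± 107 CPM (log2 fold change 3.32 ± 0.56, adjusted p = 0.0065, trend-removed 3.32 ± 0.52). Col1a1, the main chain of type I collagen, rose from 4.54 ± 0.327 to 63.4 ± 53.2 CPM (3.80 ± 0.77, adjusted p = 0.0066, trend-removed 1.29 ± 0.35). Its 3 TET2KO libraries held 4313, 301 and 2006 reads, the fewest in replicate 2. Col3a1 and Postn, which encodes periostin of activated fibroblasts, did not pass the test (0.63 ± 0.42, adjusted p = 0.21, and 0.72 ± 0.33, adjusted p = 0.087). After trend removal they passed in opposite directions, at -0.88 ± 0.22 and 1.08 ± 0.34. Without TET2KO replicate 2 both passed as counted, where the log2 fold change of Col3a1 was 0.98 and the log2 fold change of Postn was 1.01. The list median was 1.19 (camera adjusted p = 0.0075, adjusted p = 0.86 with an estimated correlation) and 0.085 after trend removal, where 8 higher and 8 lower members were counted and the list did not pass camera. On log2(TPM + 1) values it did not pass either (adjusted p = 0.065, range over 19 alternatives 9.7e-07 to 0.91).

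Of 29 TGF-beta and BMP signalling genes, 16 were higher, 0 lower and 13 not past the test (16 higher and 0 lower adjusted over the list alone) in the libraries labelled TET2KO. Ski, a repressor of SMAD proteins, rose by 3.56 ± 0.66 and Ltbp4, which binds latent TGF-beta, by 3.56 ± 0.70 on the log2 scale (trend-removed 1.54 ± 0.33 and 0.92 ± 0.25). Their median was 0.80 (camera adjusted p = 0.0075, adjusted p = 0.86 with an estimated correlation). After trend removal 6 higher and 4 lower members were counted and the list did not pass camera. Fibroblast markers had 11 higher and 5 lower of 19 (11 and 5 adjusted over the list alone, camera adjusted p = 0.34). Activated fibroblast and myofibroblast markers had 5 higher and 6 lower of 18 (5 and 6 adjusted over the list alone, camera adjusted p = 0.92), with a median of 0.21 and a mean of 0.18 against a downward camera direction. The median log2 fold change of activated fibroblast and myofibroblast markers was 0.41 without WT replicate 1, 0.095 without WT replicate 2 and 0.43 without TET2KO replicate 2. With the trend removed it turned to -0.083, where 3 higher and 7 lower members were counted. Among these markers, Ddah1, an enzyme that degrades a nitric oxide synthase inhibitor, rose by 1.87 ± 0.32 (trend-removed 1.41 ± 0.26) and Tagln, an actin-binding protein of smooth muscle, stood at -1.25 ± 0.25 (-0.71 ± 0.16).

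Genes of the heart muscle cell moved apart. Of 20 adult cardiomyocyte markers, 10 were higher, 8 lower and 2 not past the test (10 higher and 8 lower adjusted over the list alone), and the list did not pass camera (adjusted p = 0.68). The cardiac transcription factor genes Nkx2-5 and Gata4 rose by 1.81 ± 0.29 and 2.65 ± 0.47 on the log2 scale (trend-removed 1.26 ± 0.21 and 1.23 ± 0.24). Chosen after their values were seen, Myh6, the main myosin heavy chain of adult mouse ventricle, rose from 695 ± 81.4 to 7592 ± 5325 CPM (3.45 ± 0.64), while Myl2, the ventricular regulatory light chain, fell from 32056 ± 4902 to 10309 ± 4171 CPM (-1.64 ± 0.34). Across the 20 markers the fold change followed transcript length (Spearman's rho = 0.88, permutation p = 1e-05, the smallest that 100000 permutations can give, and 3e-05 adjusted over 3 such tests). The permutation treats the markers as independent, which genes measured in the same libraries are not. Trend-removed values of Myh6 and Myl2 were 1.21 ± 0.26 and -0.54 ± 0.13. With the trend removed 11 higher and 4 lower markers were counted, and the list passed camera (adjusted p = 0.96 with an estimated correlation). With the merged exon length in the trend it did not pass (adjusted p = 0.34, against 0.043, range over 19 alternatives 0.043 to 0.95).

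Fetal and hypertrophy genes, which ventricles re-express under load, had 9 higher and 4 lower of 22 (9 and 4 adjusted over the list alone, camera adjusted p = 0.52). Nppb fell from 5782 ± 894 to 1231 ± 552 CPM (log2 fold change -2.23 ± 0.39, adjusted p = 0.0065) and stayed past the test after trend removal (-1.01 ± 0.22). Nppa, which encodes atrial natriuretic peptide, fell from 1307 ± 265 to 782 ± 149 CPM (-0.74 ± 0.25, adjusted p = 0.031), with a trend-removed value of 0.35 ± 0.25. It did not pass without WT replicate 2, WT replicate 3 or TET2KO replicate 3, where the log2 fold change of Nppa was -0.62, -0.72 and -0.55. Myh7, the fetal myosin heavy chain, rose from 80.4 ± 3.93 to 319 ± 177 CPM (1.99 ± 0.43, adjusted p = 0.0074), with a trend-removed value of -0.12 ± 0.12. Acta1, the skeletal alpha-actin gene, did not pass (0.60 ± 0.27, adjusted p = 0.082) and passed after trend removal (1.01 ± 0.24). Without TET2KO replicate 2 the log2 fold change of Acta1 was 0.73, past the test. Myh7 stood at 473, 126 and 358 CPM in TET2KO replicates 1, 2 and 3.

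**Figure D2:**
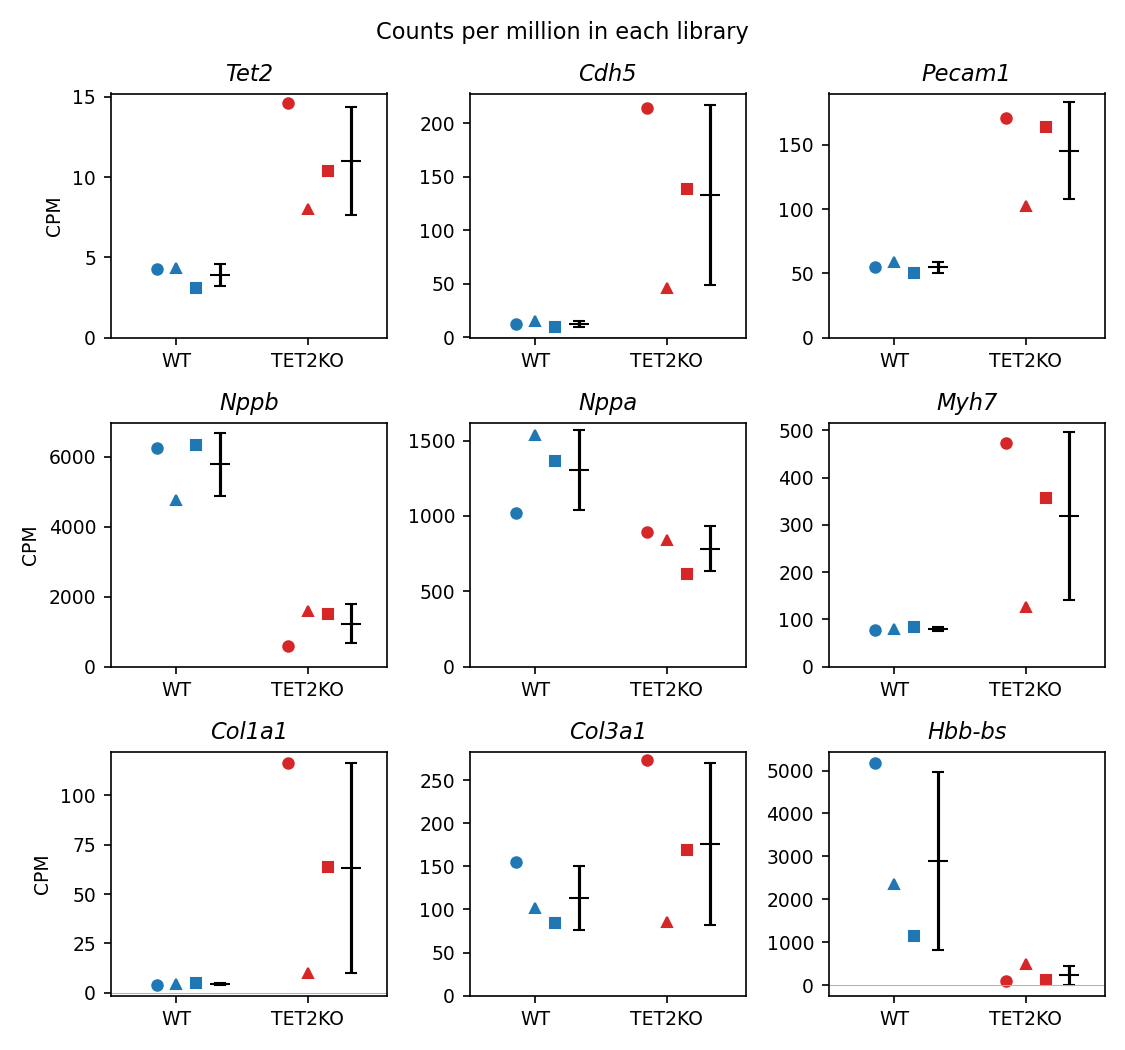
CPM (linear axes from 0) of 9 genes in each library, where circles, triangles and squares are replicates 1, 2 and 3 of WT (blue) and TET2KO (red) and black bars the mean ± SD of the 3 libraries. Tet2 lies between 3.08 and 4.33 CPM in the WT and between 8.01 and 14.6 CPM in the TET2KO libraries.

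Calcium handling and ion channel genes were mostly higher in the libraries labelled TET2KO. Of 26, 19 were higher, 4 lower and 3 not past the test (19 higher and 4 lower adjusted over the list alone). The potassium channel gene Kcnq1 rose by 2.10 ± 0.32, the sodium-calcium exchanger gene Slc8a1 by 1.68 ± 0.26, the sodium channel subunit gene Scn4b by 2.38 ± 0.32 and the junctophilin gene Jph2 by 2.19 ± 0.34 on the log2 scale. For the first 3 the trend-removed values were 1.03 ± 0.17, 1.00 ± 0.16 and 0.84 ± 0.18, past the test, and for Jph2 0.10 ± 0.14. The list median was 1.44 (camera adjusted p = 0.00074, adjusted p = 0.86 with an estimated correlation) and 0.38 after trend removal, where 12 higher and 1 lower members were counted and the list passed camera (adjusted p = 0.96 with an estimated correlation).

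Nuclear genes of oxidative phosphorylation were mostly lower in the libraries labelled TET2KO. Of 40, 1 was higher, 32 lower and 7 not past the test (1 higher and 32 lower adjusted over the list alone). Cox7a1, a cytochrome c oxidase subunit of muscle, fell from 3120 ± 513 to 838 ± 371 CPM (-1.90 ± 0.35, adjusted p = 0.0065), and the complex I subunit gene Ndufb8 stood at -1.77 ± 0.33 (trend-removed -0.61 ± 0.13 and -1.28 ± 0.20). The lengths used, of the longest transcript, were 485 nt for Cox7a1 and 2142 nt for Ndufb8. Which Ndufb8 transcript was expressed is not known, and with a shorter one the trend would take up more of its fall. The next median is that of the whole list. It was -1.31 (camera adjusted p = 4.5e-09, adjusted p = 0.86 with an estimated correlation). The median transcript of this list is 1186.5 nt long, and after trend removal 3 higher and 20 lower members were counted, with a median of -0.30, and the list passed camera (adjusted p = 0.96 with an estimated correlation). Transcripts of the mitochondrial genome took 10.1, 10.5 and 9.83% of the counts in the WT and 18.1, 14.5 and 17.1% in the TET2KO libraries. These genes had 7 higher and 1 lower of 13 (7 and 1 adjusted over the list alone, camera adjusted p = 0.26). Among them mt-Nd5, a complex I subunit, rose by 1.43 ± 0.34 (trend-removed 2.66 ± 0.43) and mt-Co3, of cytochrome c oxidase, stood at -0.75 ± 0.17 (0.35 ± 0.13). With the trend removed 11 higher and 0 lower members were counted, with a median of 1.49 against 0.64 as counted, and the list passed camera (adjusted p = 0.96 with an estimated correlation). Across these 13 genes Spearman's rho of the fold change with transcript length was 0.31 as counted (permutation p = 0.30, also 0.30 adjusted over 3 such tests) and 0.64 with the trend removed (permutation p = 0.022, 0.033 adjusted). These permutations too treat the genes as independent, which they are not. The trend was fitted to all tested genes together and need not hold for these 13. Their pass with the trend removed may therefore come from its removal.

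Other metabolic gene lists did not pass camera as counted. Fatty acid oxidation genes had 8 higher and 13 lower of 33 (8 and 13 adjusted over the list alone, camera adjusted p = 0.49), with Ppara, a transcription factor of lipid oxidation, up by 1.75 ± 0.30 and the carnitine acyltransferase gene Cpt1a by 1.86 ± 0.34 (trend-removed 1.26 ± 0.22 and 0.95 ± 0.20). The median log2 fold change of fatty acid oxidation genes, -0.35, turned to 0.078 with total library size as the scale and to 0.063 after trend removal, and was -0.18 without TET2KO replicate 1. Glycolysis and glucose uptake genes had 10 higher and 6 lower of 23 (10 and 6 adjusted over the list alone, camera adjusted p = 0.38), with the hexokinase gene Hk1 up by 2.51 ± 0.37 (trend-removed 0.88 ± 0.13). Adipocyte markers had 4 higher and 0 lower of 10 (4 and 0 adjusted over the list alone, camera adjusted p = 0.096), among them the triglyceride lipase gene Pnpla2 at 2.35 ± 0.33 (trend-removed 1.56 ± 0.20). That list passed camera (adjusted p = 0.96 with an estimated correlation) after trend removal, with a median of 1.01. At the preset correlation it also passed without TET2KO replicate 1 or TET2KO replicate 2, with medians of 1.06 and 1.31, while all 6 libraries gave adjusted p = 0.86 with an estimated correlation. Without TET2KO replicate 3 the median log2 fold change of adipocyte markers was 0.56 and the list did not pass (adjusted p = 0.21, range over 19 alternatives 0.0048 to 0.21).

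Erythrocyte transcripts were lower in the libraries labelled TET2KO. Of 8, 0 were higher, 8 lower and 0 not past the test (0 higher and 8 lower adjusted over the list alone). Hbb-bs fell from 2900 ± 2071 to 235 ± 222 CPM (-3.62 ± 0.81, adjusted p = 0.0079) and Hbb-bt from 208 ± 139 to 20.7 ± 18.2 CPM (-3.33 ± 0.73, adjusted p = 0.0075). Hbb-bs and Hbb-bt, like Hba-a1 and Hba-a2, are near-identical genes whose reads the counting could split between them. In the WT libraries Hbb-bs ranged from 1149 to 5186 CPM. The 8 members had a median of -2.87 (camera adjusted p = 0.0020, adjusted p = 0.86 with an estimated correlation). After trend removal 0 higher and 8 lower members were counted, with a median of -1.95, and the list passed camera (adjusted p = 0.96 with an estimated correlation). Without TET2KO replicate 2 it did not pass (median -3.45, adjusted p = 0.054, range over 19 alternatives 1.7e-07 to 0.054).

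Immune gene lists did not pass camera. Inflammatory cytokine and NF-kB genes had 5 higher and 11 lower of 22 (5 and 11 adjusted over the list alone, camera adjusted p = 0.31), among them Il1b, the cytokine interleukin-1 beta (-2.63 ± 0.39), and Casp1, the protease that matures it (-1.67 ± 0.30). After trend removal 4 higher and 2 lower members of this list were counted, and its median went from -0.89 to -0.035. Macrophage and monocyte markers had 6 higher and 5 lower of 24 (6 and 5 adjusted over the list alone, camera adjusted p = 0.52), with the lysozyme gene Lyz2 at -1.60 ± 0.32 and Csf1r, a receptor that sustains macrophages, at 1.96 ± 0.42. Trend-removed values were -1.60 ± 0.38 for Il1b, -0.58 ± 0.23 for Casp1 (not past the test), -0.71 ± 0.14 for Lyz2 and 0.46 ± 0.22 for Csf1r (not past the test).

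Of 22 immediate early genes, among the first genes induced by many stimuli, 13 were higher, 0 lower and 9 not past the test (13 higher and 0 lower adjusted over the list alone) in the libraries labelled TET2KO. Nr4a3 rose by 2.40 ± 0.32, Jund by 1.84 ± 0.26 and Jun by 1.96 ± 0.37 on the log2 scale (trend-removed 1.40 ± 0.24, 1.15 ± 0.16 and 1.02 ± 0.28). These genes had a median of 1.48 (camera adjusted p = 0.0075, adjusted p = 0.86 with an estimated correlation). After trend removal 10 higher and 0 lower members were counted and the list passed camera (adjusted p = 0.96 with an estimated correlation). The median log2 fold change of immediate early genes was 0.81 without TET2KO replicate 1, and without TET2KO replicate 2, or with sample quality weights in limma-voom, the list did not pass (adjusted p = 0.16 and 0.083, range over 19 alternatives 4.4e-06 to 0.16). Of 19 circadian clock genes, 12 were higher, 1 lower and 6 not past the test (12 higher and 1 lower adjusted over the list alone). The clock repressor gene Cry2 rose by 2.41 ± 0.39 and Bhlhe40, another transcriptional repressor, by 1.85 ± 0.27 (trend-removed 1.02 ± 0.19 and 1.69 ± 0.23). Clock genes had a median of 1.32 (camera adjusted p = 0.019, adjusted p = 0.86 with an estimated correlation). After trend removal 7 higher and 4 lower members were counted and the list did not pass camera. It did not pass on log2(TPM + 1) or log2(TPM + 0.1) values either (adjusted p = 0.065 and 0.073, range over 19 alternatives 3.3e-05 to 0.24). Without TET2KO replicate 1 the median log2 fold change of circadian clock genes was 0.74.

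**Figure D3:**
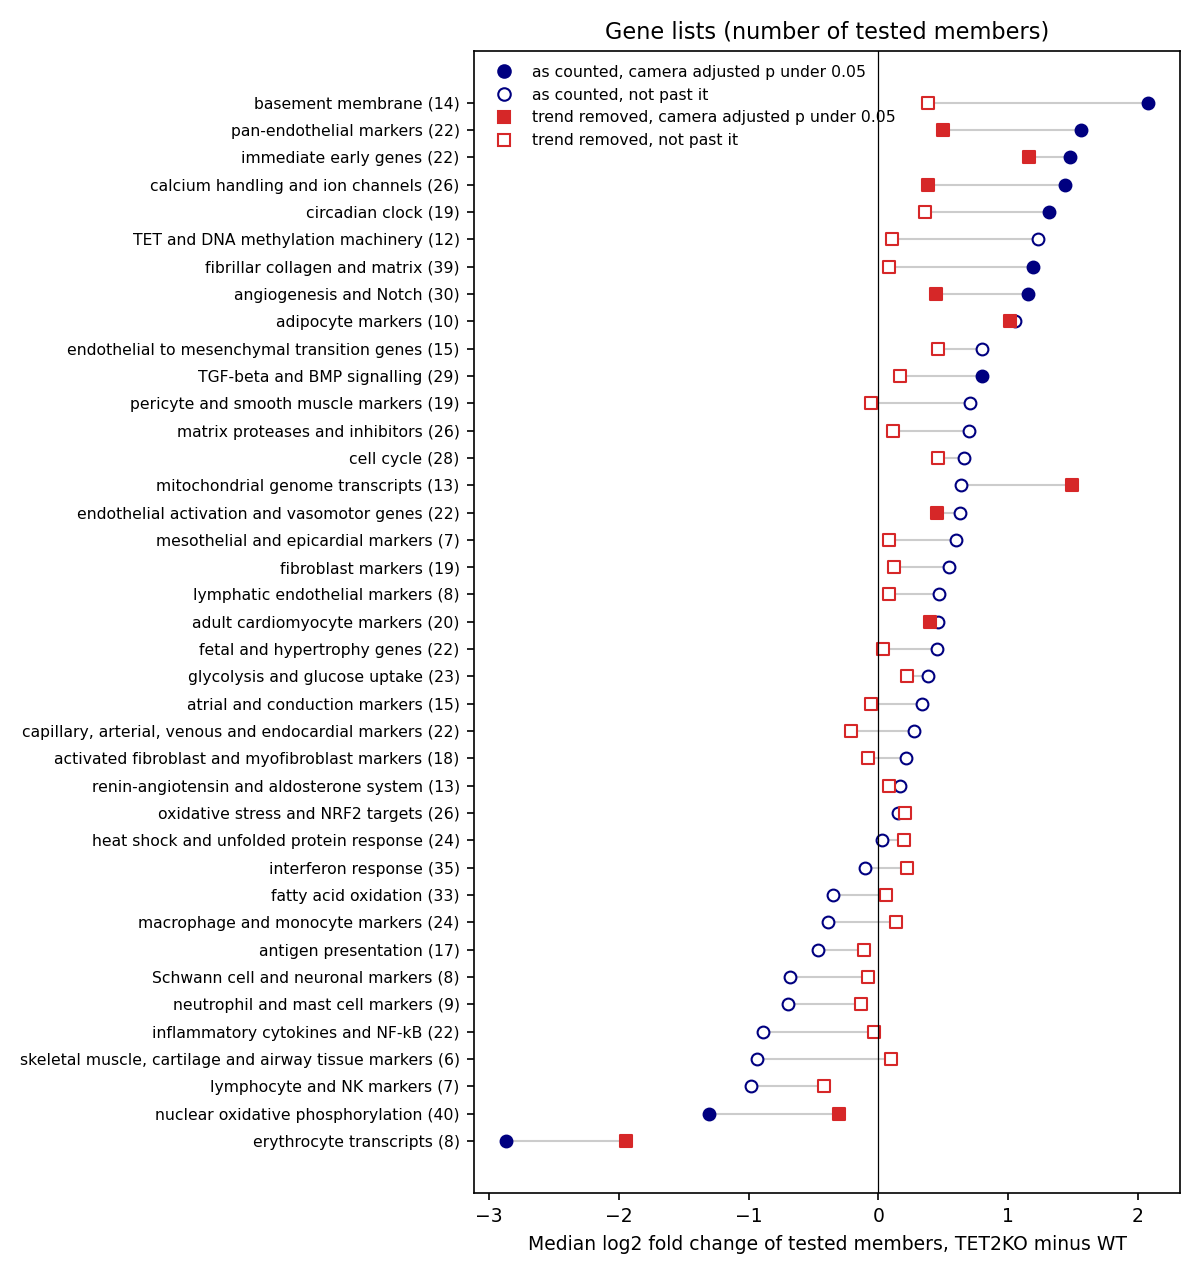
Median log2 fold change (TET2KO minus WT, x axis) of the tested members of 39 gene lists (y axis, with the number tested), where circles are as counted and squares have the length and GC trend removed, filled where camera passed at an adjusted p under 0.05. Medians as counted run from -2.87 for erythrocyte transcripts to 2.08 for basement membrane genes.

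The authors' deposited table lists 14370 genes, of which 9346 had an adjusted p under 0.05. In the authors' deposited table of significant genes there are 6254, with 3450 higher and 2804 lower in TET2KO. The smallest absolute log2 fold change among these is 1.00, while the 9346 were counted without a limit on the fold change. With an absolute log2 fold change of at least 1, edgeR called 6125. Of 14196 genes tested in both the authors' deposited table and edgeR, 8851 were called in both, 8851 of them with the same sign. The authors' deposited table gives log2 fold changes of 1.44 for Tet2, 3.33 for Cdh5, -2.28 for Nppb and 3.74 for Col1a1.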

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

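The removal of the length and GC trend, and the gene lists at total library size, were chosen after the results had been seen; the other alternatives were fixed before. Between 5074 and 11746 genes passed across 21 alternatives, and 4036 to 8672 with the trend removed and 1 library left out as well, and of the genes called in both fits none (0) changed direction under one fixed before. At an adjusted p under 0.01 the count was 5074, with 2865 higher and 2209 lower. With an absolute log2 fold change of at least 1 as well, 2597 were lower. Lower genes numbered 2270 with total library size, 1832 on log2(TPM + 1) and 1882 on log2(TPM + 0.1), where 7270 were higher; the cause was not tested. Leaving out 1 library gave 6133 to 11178 genes, 3370 to 5928 of them higher and 2479 to 5250 lower; the 2479 came without TET2KO replicate 3 and 2771 without WT replicate 3, with fewer samples. With the trend removed 3150 were higher.

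Tet2 passed in all 17 alternatives fixed before (log2 fold change 0.92 to 1.93; adjusted p 2.1e-06 to 0.035), and stood at 0.27 with the trend removed and 0.38 with merged exons (adjusted p = 0.21 and 0.096), where the fold change itself fell by more than its SE of 0.29. Named genes that turned with the trend removed were Tet3 (-0.013), Nppa (0.35; 0.38 with merged exons), Myh7 (-0.12), Col3a1 (-0.88; -0.86), Lamb2 (-0.020), mt-Co3 (0.35; 0.34) and Myl1 (0.12). A further 15 of 114 called named genes no longer passed. The alternatives fixed before took 0 to 10 of these calls and reversed 0.

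Of the 39 lists tested, 10 passed camera at the preset correlation, 0 with an estimated correlation (0 at an unadjusted p under 0.05; smallest adjusted p = 0.86) and 0 by fry (15 at an unadjusted p under 0.05; smallest adjusted p = 0.11). At the preset correlation, leaving out 1 library gave 10 to 11 lists. Without the count filter 9 further lists passed at the preset correlation, where the median log2 fold change of TET and DNA methylation machinery, 1 of them, was 1.30, and 0 lost their call; the cause was not tested. The lists were not tested with an estimated correlation without the count filter, and with the filter the TET list had adjusted p = 0.86 with an estimated correlation. With the trend removed 10 lists passed at the preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.96). Basement membrane, fibrillar collagen, TGF-beta and circadian lists no longer passed, and adipocyte, endothelial activation, mitochondrial genome and adult cardiomyocyte lists did, the last not with merged exons. On log2(TPM + 1) the fibrillar collagen, pan-endothelial and circadian lists did not pass. The mitochondrial genome list passed there at the preset correlation (median 1.27, camera adjusted p = 0.037), where no estimated correlation was run.

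With the replicate number as a block, 7618 genes passed, 7551 of them shared, and Tet2 stood at 1.47. Same-numbered libraries did not deviate together from their group means (correlations 0.039, -0.23 and -0.013), and WT replicate 2 correlated best with TET2KO replicate 1 (0.26). The numbers were therefore treated as names only. Deviations from means of 3 libraries cannot show whether same-numbered samples were handled together. The alternative with sex as a covariate was not run, since all 6 libraries held Y-linked Ddx3y reads (891 to 2384) and at most 4 Xist reads. In data simulated without a trend, with the dispersions of the main fit, 30% of genes changed by a log2 fold of 1 were found. With a trend added and the dispersions of the trend-removed fit, 69% were found as counted, where 6406 unchanged genes were called too. With that trend removed 82% were found. Changes of this size or smaller can thus be missed, to an extent that depends on the dispersions used.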

Other observations

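All tests of explanations below were chosen after the results had been seen. Several gene groups have not been described so far. Interferon response genes had 10 higher and 8 lower of 35 (9 and 4 adjusted over the list alone, camera adjusted p = 0.99), with a median of -0.11, a mean of 0.11 and a downward camera direction. The sign was not stable: the median log2 fold change of interferon response genes was 0.051 without TET2KO replicate 1 and 0.22 with the trend removed, and -0.022, -0.023 and -0.068 without WT replicate 2, WT replicate 3 and TET2KO replicate 3. With the trend removed 14 higher and 4 lower members were counted, and the list did not pass camera (adjusted p = 0.055). Among interferon response genes, the RNA sensor gene Ddx58 rose by 2.52 ± 0.41 and Oas2, which makes a second messenger of antiviral defence, by 2.60 ± 0.46 on the log2 scale (trend-removed 2.29 ± 0.35 and 1.93 ± 0.37). Antigen presentation genes had 5 higher and 7 lower of 17 (5 and 8 adjusted over the list alone, camera adjusted p = 0.85), with a median of -0.47, a mean of 0.020 and a downward camera direction. The median log2 fold change of antigen presentation genes was -0.24 both without WT replicate 2 and without TET2KO replicate 1. Cd74, a chaperone of MHC class II, rose by 1.13 ± 0.18. Renin-angiotensin and aldosterone genes had 5 higher and 2 lower of 13 (5 and 2 adjusted over the list alone, camera adjusted p = 0.86). Ace, the angiotensin-converting enzyme, rose by 2.99 ± 0.55 and Rgs2, which dampens signalling of the angiotensin receptor, stood at -1.55 ± 0.24 (trend-removed 1.19 ± 0.26 and -1.13 ± 0.16). Oxidative stress and NRF2 target genes had 6 higher and 6 lower of 26 (6 and 6 adjusted over the list alone, camera adjusted p = 0.94), with a median of 0.15 and a mean of 0.016 against a downward camera direction. The median log2 fold change of oxidative stress and NRF2 targets was 0.0099 without WT replicate 1 and 0.24 without TET2KO replicate 1. Sod3, the extracellular superoxide dismutase, rose by 2.78 ± 0.39 and the glutathione transferase gene Gstm1 by 1.59 ± 0.24 (trend-removed 1.94 ± 0.26 and 2.40 ± 0.29).

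Pericyte and smooth muscle markers had 11 higher and 4 lower of 19 (12 and 5 adjusted over the list alone, camera adjusted p = 0.22), and Myh11, the smooth muscle myosin, rose by 3.54 ± 0.65 (trend-removed 1.63 ± 0.34). At the preset correlation the list passed camera without TET2KO replicate 2, where the median log2 fold change of pericyte and smooth muscle markers was 0.90, while all 6 libraries gave adjusted p = 0.86 with an estimated correlation. After trend removal 6 higher and 6 lower members were counted, and the median went from 0.71 with all libraries to -0.059. Matrix proteases and inhibitors had 13 higher and 5 lower of 26 (13 and 5 adjusted over the list alone, camera adjusted p = 0.31), and the membrane-bound protease gene Mmp15 rose by 3.43 ± 0.56 (trend-removed 1.13 ± 0.17). Schwann cell and neuronal markers had 0 higher and 4 lower of 8 (3 and 5 adjusted over the list alone, camera adjusted p = 0.47), and Dbh, the noradrenaline-forming enzyme of sympathetic nerves, stood at -1.31 ± 0.26 (trend-removed -1.81 ± 0.29). Genes of the endothelial to mesenchymal transition had 8 higher and 2 lower of 15 (8 and 2 adjusted over the list alone, camera adjusted p = 0.31), and the N-cadherin gene Cdh2 rose by 1.70 ± 0.32 (trend-removed 0.78 ± 0.18). Other lists were heat shock and unfolded protein response with 6 higher and 5 lower of 24 (5 and 4 adjusted over the list alone, camera adjusted p = 0.86), and cell cycle with 8 higher and 3 lower of 28 (5 and 3 adjusted over the list alone, camera adjusted p = 0.49). Atrial and conduction markers had 6 higher and 3 lower of 15 (6 and 3 adjusted over the list alone, camera adjusted p = 0.52), lymphatic endothelial markers 3 higher and 1 lower of 8 (3 and 1 adjusted over the list alone, camera adjusted p = 0.62), and mesothelial and epicardial markers 3 higher and 2 lower of 7 (3 and 2 adjusted over the list alone, camera adjusted p = 0.94). Neutrophil and mast cell markers had 1 higher and 4 lower of 9 (1 and 4 adjusted over the list alone, camera adjusted p = 0.33), lymphocyte and NK markers 0 higher and 3 lower of 7 (0 and 1 adjusted over the list alone, camera adjusted p = 0.29), and markers of skeletal muscle, cartilage and airway 0 higher and 3 lower of 6 (0 and 2 adjusted over the list alone, camera adjusted p = 0.31).

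Most of the tested genes passed the test, 9037 in all, with fold changes that followed transcript length. A smooth trend on the length and GC of the longest transcript did not take up all calls. With it removed 6647 genes passed (4221 without WT replicate 1, 4259 without WT replicate 3, 4036 without TET2KO replicate 3). The longest transcript need not be the one expressed, so this does not exclude a length effect as the whole cause. A changed share of cardiomyocytes alone is not the whole cause, since 8 adult cardiomyocyte markers fell while 10 rose. With the trend removed 4 fell and 11 rose. Fold changes of these markers as counted followed transcript length, so a changed share beside a length effect is not excluded. A difference in RNA integrity or library preparation is a candidate explanation: the difference between TET2KO replicates 1 and 2 followed that between TET2KO replicate 3 and the WT mean, which share no library, at Spearman's rho = 0.91 across genes (0.79 with the trend removed), though a genotype effect of unequal strength would give the same, was not tested and stays open. The real split of the 6 libraries was 1 of 10 splits, too few for a share under 0.05, and called 9037 genes as counted and 6647 with the trend removed, where the highest other split called 0 with edgeR in each (1030 at an unadjusted p under 0.05 as counted, with no other tool run on the splits). For lists passing camera at the preset correlation the real split gave 10. Of the 10 splits, the real one included, 5 gave 10 or more, and the highest other gave 16. The number of lists passing camera at that correlation therefore did not set the genotype split apart from other splits.

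Tet2 was higher in the libraries labelled TET2KO. The length and GC trend is a candidate explanation, since Tet2 lay at percentile 64.5 of the fold changes of the 200 tested genes nearest to it in length and GC, whose median was 1.21. Genotype labels exchanged between the groups cannot be told apart from correct ones, since the trend-removed value of 0.27 ± 0.17 passed the test in neither direction. An endothelial deletion diluted in whole tissue, or one that leaves most exons in the transcript, was not tested and stays open.

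Erythrocyte transcripts were lower in the libraries labelled TET2KO, though without TET2KO replicate 2 the list, with a median of -3.45, did not pass camera. The fitted trend on the length and GC of the longest transcript is not the whole cause, since the list median was -1.95 with it removed and 8 of 8 members still passed. Blood cell RNA retained in unequal amounts is a candidate source, since 8 of the 8 members ordered the 3 WT libraries alike. The most abundant, Hbb-bs, stood at 5186, 2364 and 1149 CPM and Hba-a1 at 1200, 589 and 259 CPM in WT replicates 1, 2 and 3. That 0 of the members are in another list was fixed with the lists and bears on no source. A difference in circulating or developing red cells would order the WT libraries alike too, was not tested and stays open. In TET2KO replicates 1, 2 and 3 Hbb-bs stood at 89.5, 490 and 125 CPM. Each member was highest there in replicate 2, the TET2KO library that correlated most closely with the WT libraries across genes. A difference in RNA integrity or library preparation beyond the fitted trend was not tested for these transcripts and stays open too.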
